A study of Caenorhabditis elegans with 27 samples.

How the data were processed

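The files hold gene counts for 27 libraries of poly(A) RNA from whole worms, with 3 libraries for each of 9 RNAi feeding groups. The N2 worms, with an hsp-6::GFP reporter per the series design, were fed from the egg stage at 20 degrees and collected after 2 days as L4 larvae or young adults, per the labels. The mixtures with cbp-1 held 25% of that clone and the mixtures with atfs-1 held 50%, per the labels, which give no share for either clone alone. Reads were aligned with STAR 2.6.0a and counted per gene with HTSeq 0.10.0 on WBcel235, per the submitters' processing notes. The deposited values are these counts, unscaled. The tool for read trimming is not given in the sources used here.

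The table holds 46738 genes, of which 43719 matched the reference name table and 210 have a blank symbol. Sequence names were kept where the table uses them. The table's summary lines for reads without a feature, ambiguous reads and reads without a unique alignment held 8.71% to 17.0% of all reads in the table (median 10.2%) and were left out of library sizes and tests. Gene counts summed to 20672073 to 30938572 per library (median 27527028), and the 10 highest genes took 5.02% to 10.6% of them. The common biological coefficient of variation was 4.18%. Pairs of replicates differed by more than counting noise, with chi-square per degree of freedom of 1.45 to 6.42 outside the atfs-1 group and at most 29.9 within it, for genes with at least 20 counts.

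Genes were tested in R 4.3.3 with edgeR 4.0.16. The filter filterByExpr on the group, with a minimum count of 10, kept 16435 genes. TMM factors, robust quasi-likelihood fits over all 27 libraries with 1 coefficient per group, and quasi-likelihood F tests gave log2 fold changes, standard errors and p-values. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. CPM values are given as mean ± SD of 3 libraries. The 15 comparisons were each single clone against the empty vector, each mixture against its mitochondrial clone, the cbp-1 mixture against the atfs-1 mixture in each arm, mrps-5 against cco-1, and 4 interaction terms. Genes raised by cco-1 or mrps-5 were those called with a log2 change of at least 1, and the percent of them called lower in each mixture was counted, beside simulations that kept the rise and left the mixture unchanged.

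Gene lists were written from general knowledge of worm genes, and 36 were used. The RNAi targets (4 genes) and the cbp-1 homologs (2 genes) are given gene by gene, and the other 34 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. They cover mitochondrial chaperones and proteases, mitochondrial stress regulators, mitochondrial protein import, cytosolic heat shock, endoplasmic reticulum stress, glycolysis, tricarboxylic acid and glyoxylate cycles, nuclear oxidative phosphorylation, mitochondrial DNA encoded genes, mitochondrial and cytosolic ribosomes, proteasome, autophagy and lysosome, cytochrome P450, UDP-glucuronosyltransferase, glutathione transferase, antioxidant, innate immunity, hypoxia, DAF-16, fatty acid and lipid, one-carbon, vitellogenin, collagen, molting, oocyte and early embryo, germline, sperm, intestine, muscle, neuron, hypodermis, RNA interference and histone genes. Counts of members are given over all genes and, where stated, adjusted over the list alone. Named genes are the 4 targets, the 12 chaperones and proteases, up to 4 members of each list with the smallest adjusted p, and the 5 largest rises and falls with a mean of at least 5 CPM; others are stated to be chosen after their values were seen.

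These groups, comparisons, lists and the naming rule were fixed before the data were examined, as were these alternatives: DESeq2 1.42.0, RLE and upper-quartile scaling, no filter or a stricter filter of 5 CPM in 3 libraries, only the groups compared, a replicate block, leaving out each library, a raised set at a log2 change of 2, and a call by the interaction term. A term for the library set, a raised set from that fit and a test of the difference between arms were added after the data were seen. The steps were tested on simulated data made from the real means with 200 changed genes. For cco-1 against the empty vector, on 16131 genes, 100% of genes changed 1.5-fold and 99% of those changed 2-fold were recovered, with 8 false calls (3.86% of calls). For the interaction of cco-1 and cbp-1, on 16146 genes, these were 90% and 99%, with 11 false calls (5.5%). In both, a raised list was called and 20 unchanged lists were tested, of which 0 were called. Each gene was drawn independently and no library sets were simulated. These rates therefore do not cover false calls from genes that vary together or from library sets.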

Results

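The 27 libraries cover 9 RNAi feeding groups, 3 each. Single groups received the empty vector, cco-1, mrps-5, cbp-1 or atfs-1 clones, and mixed groups cco-1 or mrps-5 with cbp-1 or atfs-1. cco-1 (also named cox-5B) encodes a subunit of cytochrome c oxidase and mrps-5 a protein of the mitochondrial ribosome, so both clones disturb mitochondria. cbp-1 encodes the worm homolog of the acetyltransferases CBP and p300, and atfs-1 encodes a transcription factor that activates mitochondrial chaperone genes under mitochondrial stress. The comparisons of 16435 genes ask which respond to each mitochondrial clone and how far these responses depend on cbp-1 or atfs-1.

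The mitochondrial Hsp70 gene hsp-6 rose by 0.70 ± 0.05 (log2 fold change ± standard error, n = 3 per group) in cco-1 worms. The rise in mrps-5 worms was 0.74 ± 0.05. Both rises cross the library sets described below and were smaller with the library-set term. hsp-6 was lower by 0.50 ± 0.05 and 0.43 ± 0.05 in the mixtures of cco-1 and mrps-5 with cbp-1. In those labelled with atfs-1 the falls were 0.45 ± 0.05 and 0.34 ± 0.05. The atfs-1 read count was not lower in these mixtures, which does not show whether the worm transcript fell. Against the empty vector 9646 genes changed in cbp-1 worms (edgeR adjusted p below 0.05). In cco-1 worms 7449 changed (2691 with the term), in mrps-5 worms 6225 (1602) and in the libraries labelled atfs-1 RNAi 1772. The p-values measure only the spread between these libraries, which may be technical, since the labels do not name separate cultures.

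The libraries fell into a pair of sets that the groups do not fully explain. Their axis was the log2 difference between the first library labelled atfs-1 RNAi and its replicates, over 393 genes above 0.5 in size. It parts these 3 by construction, so their placement is not a finding. The first of them, the 3 empty vector and the 3 cbp-1 libraries scored 0.35 to 0.45, and the other 20 libraries -0.24 to -0.09. The gene rpl-37, which encodes a cytosolic ribosomal protein, had at most 3.48 log2 CPM in the first set and at least 5.28 in the second. The axis followed gene length, with Spearman's rho of -0.59 across genes, which are not independent replicates; single libraries against their own group reached a size of at most 0.321. Comparisons of cco-1, mrps-5 or the libraries labelled atfs-1 RNAi with the empty vector cross the sets. A term for the library set was added to the fit after the data were seen, and for named genes its value is also given where it ends a call or moves the value by over 1.5 times. That term rests on the atfs-1 group, the 1 group with libraries in both sets. With it, the atfs-1 change against the empty vector is that of 1 library, the first, against 3, and this library is assumed to vary like the other groups. The cbp-1 comparison with the empty vector and the comparisons of mixed groups with their own mitochondrial clone lie within 1 set.

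**Figure D1:**
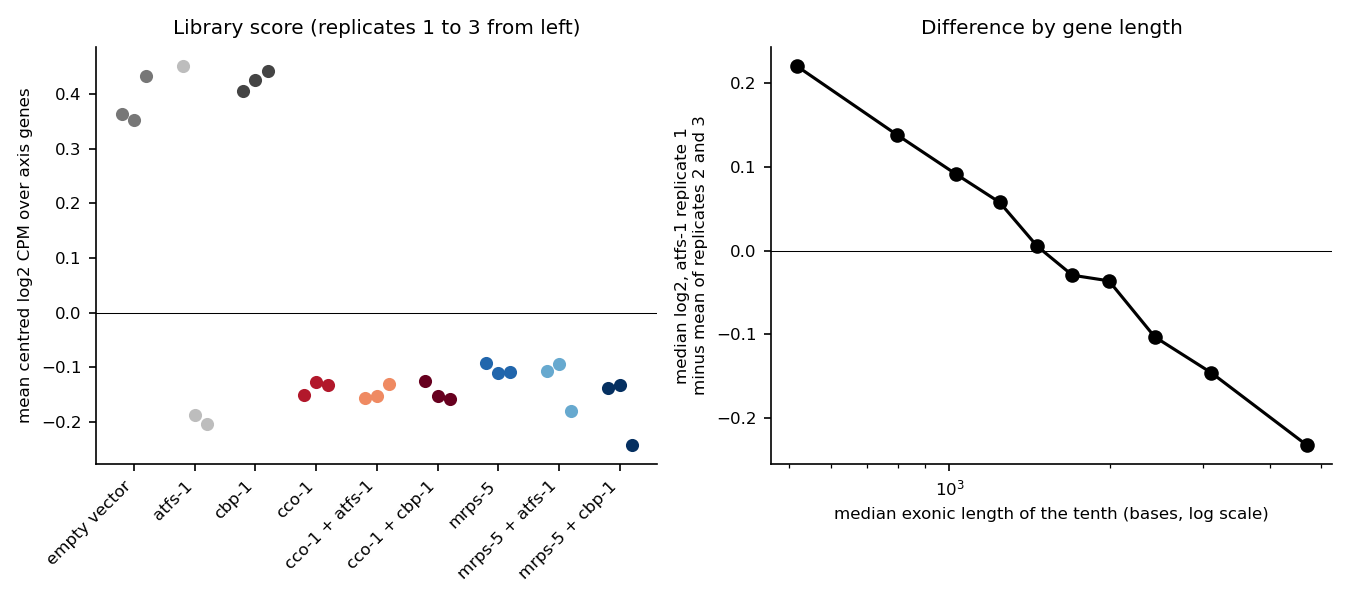
Left, the score of each library on the axis between the sets, as the mean centred log2 CPM of 393 genes, by group; 7 libraries score at least 0.35 and 20 score at most -0.09. Right, the median log2 difference between the first library labelled atfs-1 RNAi and the mean of the other 2, in 10 equal bins of gene length; it runs from 0.22 in the shortest to -0.23 in the longest.

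The targeted genes were read first. cco-1 (WBGene00000371, chromosome I, 9788725 to 9790050 in WBcel235) had 302 ± 8.62 CPM (mean ± SD, n = 3) in the empty vector and 169 ± 1.87 in cco-1 worms. The change was -0.83 ± 0.12 (adjusted p = 9.33e-06) and -0.16 with the library-set term (adjusted p = 0.149). Against mrps-5 worms, which lie in the same set, cco-1 worms had the lower cco-1 value (0.34 ± 0.12 for mrps-5 minus cco-1, adjusted p = 0.0715), which did not pass; with the term it passed (0.34, adjusted p = 3.00e-07). mrps-5 (WBGene00008452, chromosome V, 12563487 to 12565801) fell from 105 ± 3.59 to 83.2 ± 3.44 CPM (-0.33 ± 0.04, adjusted p = 7.60e-09; -0.32 with the library-set term, adjusted p = 8.95e-05). cbp-1 (WBGene00000366, chromosome III, 9766509 to 9774825) fell from 269 ± 10.5 to 208 ± 2.23 CPM in cbp-1 worms (-0.37 ± 0.06, adjusted p = 3.58e-05). It fell by 0.24 ± 0.06 and 0.22 ± 0.06 where the cbp-1 clone was added to cco-1 or mrps-5. The read count of atfs-1 (WBGene00013878, chromosome V, 14193663 to 14197700) did not fall in the libraries labelled atfs-1 RNAi. This count was 77.7 ± 1.06 CPM in the empty vector and 90.5 ± 4.05 in those libraries (0.22 ± 0.04, adjusted p = 0.000298; 0.15 with the library-set term). It was also higher by 0.18 ± 0.04 in the cco-1 mixture with atfs-1 and moved by 0.05 ± 0.04 in the mrps-5 mixture (adjusted p = 0.453). The atfs-1 groups are therefore named by their labels, and their comparisons are not taken as comparisons at a lower atfs-1 transcript.

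In cco-1 worms, mitochondrial chaperone and protease genes rose and vitellogenin genes, which encode yolk proteins, fell. hsp-6 rose by 0.70 ± 0.05 (adjusted p = 6.19e-16, 0.40 with the library-set term, n = 3 per group), the mitochondrial DnaJ gene dnj-10 by 0.71 ± 0.04 (0.62 with the term) and the mitochondrial protease gene spg-7 by 0.68 ± 0.06 (0.26). The yolk gene vit-3 fell by 3.90 ± 0.06 (-3.91 with the term) and fat-7, which encodes a fatty acid desaturase, by 4.47 ± 0.08 (-4.49). Of 7449 changed genes 3795 rose and 3654 fell; with the library-set term 1133 rose and 1558 fell, and 2149 genes were called the same way in both fits. Of the 12 chaperones and proteases, 11 rose and K07A3.3 did not pass (0.21 ± 0.10); 12 rose adjusted over the list alone. The list ranked high by camera (adjusted p = 2.91e-06, adjusted p = 0.0575 with an estimated correlation). With the term 9 members rose, and hsp-60, the mitochondrial chaperonin gene, gave 0.05 instead of 0.79 and D2030.2 (clpx-1) 0.05 instead of 0.63.

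Mitochondrial import, cycle and cytosolic heat shock lists were called Up in cco-1 worms, and of these the heat shock call alone held with an estimated correlation. Of 12 mitochondrial import genes 10 rose and 1 fell over all genes and adjusted over the list alone (camera adjusted p = 0.00216, adjusted p = 0.0581 with an estimated correlation). Among them were E04A4.5 (timm-17B.1, 0.59 ± 0.04), the outer membrane receptor gene ZK370.8 (tomm-70, 0.79 ± 0.06; 0.45 with the library-set term) and tin-44 (0.38 ± 0.04). The small heat shock genes hsp-16.2 and hsp-16.41 rose by 4.02 ± 0.12 and 3.51 ± 0.14, and hsp-70 by 1.66 ± 0.14 (1.01 with the term). Of the cytosolic heat shock list 5 of 14 genes rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.00216, adjusted p = 0.0193 with an estimated correlation). Among genes of the tricarboxylic acid and glyoxylate cycles 13 of 25 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0259, adjusted p = 0.699 with an estimated correlation). idh-1 gave 0.68 ± 0.03 and icl-1, the glyoxylate cycle gene, 0.91 ± 0.05.

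Yolk, lipid and immune lists were called Down in cco-1 worms, and of these the yolk call alone held with an estimated correlation. All 6 vitellogenin genes fell (median -2.48; -2.71 with the library-set term; camera adjusted p = 5.59e-62, adjusted p = 1.58e-05 with an estimated correlation), with vit-1 at -2.59 ± 0.06 and vit-4 at -2.92 ± 0.06. Of 81 genes for fatty acid desaturation and lipid breakdown 21 rose and 32 fell (22 and 33 adjusted over the list alone; camera Down, adjusted p = 0.00232, adjusted p = 0.0581 with an estimated correlation). acs-22 fell by 2.09 ± 0.05 and cpt-5 by 1.60 ± 0.06, while the acyl-CoA synthetase gene acs-2 rose by 3.78 ± 0.08; the list's median, -0.0003, becomes 0.03 with upper-quartile scaling. Of 244 innate immunity genes 49 rose and 90 fell (51 and 91 adjusted over the list alone; camera adjusted p = 0.0123, adjusted p = 0.0581 with an estimated correlation). Among them were the lysozyme genes lys-7 (-2.88 ± 0.05) and lys-4 (-2.48 ± 0.06) and the lectin gene clec-4 (4.68 ± 0.08). The metallothionein genes mtl-1 and mtl-2 fell by 2.21 ± 0.16 and 1.71 ± 0.06. In all 8 of 18 DAF-16 associated genes fell and 5 rose, over all genes and adjusted over the list alone (camera adjusted p = 0.0259, adjusted p = 0.258 with an estimated correlation). Cytosolic ribosome genes fell in 71 of 81 members (camera adjusted p = 5.12e-09, adjusted p = 0.756 with an estimated correlation) and histone genes in 19 of 40 (camera adjusted p = 0.019, adjusted p = 0.756 with an estimated correlation). Neither kept its call with the library-set term, where their medians were -0.07 and -0.06.

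The largest changes in cco-1 worms were in genes of several kinds. F22B3.7 rose by 6.41 ± 0.14, B0205.13 by 5.21 ± 0.09 and B0205.14 by 5.19 ± 0.20 (all 3 also called with the library-set term), and the cytochrome P450 genes cyp-14A4 and cyp-33C8 by 4.84 ± 0.09 and 4.31 ± 0.05. cyp-13A8 rose by 5.404 ± 0.16, which did not pass with the term (3.80, adjusted p = 0.0665). F26E4.16 rose further (8.57 ± 0.62; 8.503 with the term, adjusted p = 0.5). This short non-coding RNA (chromosome I, 9789221 to 9789490) lies on the same strand inside the cco-1 locus. Reads from the fed clone were not told apart from worm reads, so the values of the 4 targets are not measures of the worm transcript alone. Large falls were in the thaumatin family genes thn-2 (-4.54 ± 0.11) and thn-1 (-4.46 ± 0.16), fat-7 (-4.47 ± 0.08), the sphingomyelinase gene asm-3 (-4.46 ± 0.07) and the dehydrogenase gene dhs-26 (-4.24 ± 0.09). Nuclear oxidative phosphorylation genes split, 14 up and 18 down of 53 (median -0.01, camera adjusted p = 0.959), with cyc-1 at 0.27 ± 0.03 and ucr-2.3 at -0.34 ± 0.04. With the term 20 rose and 0 fell, the list was called Up (adjusted p = 0.000124, adjusted p = 0.472 with an estimated correlation) and ucr-2.3 lost its call (-0.08, adjusted p = 0.359). The collagen, molting, oocyte and early embryo, sperm and muscle lists had medians of 0.06, 0.15, -0.09, 0.12 and -0.16 and were not called (adjusted p = 0.959, 0.271, 0.42, 0.394 and 0.258); with the term the sperm list was called (adjusted p = 0.0131, adjusted p = 0.693 with an estimated correlation). In all 14 lists were called with the term in cco-1 worms and 11 in mrps-5 worms, 8 and 5 of them also without it.

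**Figure D2:**
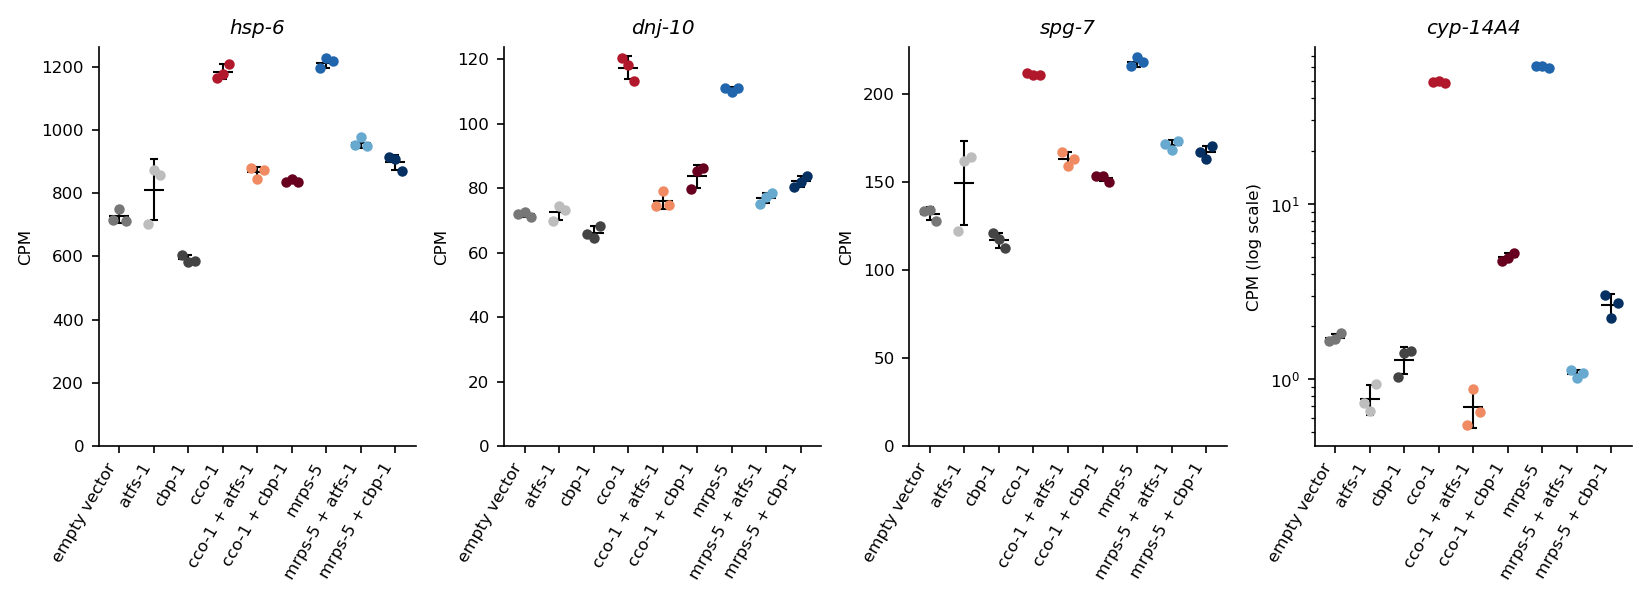
CPM of hsp-6, dnj-10, spg-7 and cyp-14A4 in each of the 27 libraries by group (points), with the mean and SD of 3 libraries; cyp-14A4 is on a log scale. Each gene is higher in cco-1 and mrps-5 worms than in the empty vector and lower again in the mixtures labelled with cbp-1 or atfs-1.

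In mrps-5 worms the same chaperones rose, with smaller losses of yolk transcripts and more mitochondrially encoded RNA. hsp-6 rose by 0.74 ± 0.05 (adjusted p = 3.36e-16, 0.44 with the library-set term, n = 3 per group), dnj-10 by 0.62 ± 0.04 (0.54) and the GrpE-like gene C34C12.8 by 0.51 ± 0.04 (0.49). The mitochondrially encoded genes nduo-4, atp-6 and ctc-2 rose by 1.57 ± 0.13, 1.09 ± 0.09 and 0.94 ± 0.07 (0.81, 0.88 and 0.75 with the term). Of 6225 changed genes 3115 rose and 3110 fell; with the term 706 rose and 896 fell, and 1202 were called the same way in both fits. Of the 12 chaperones and proteases 11 rose, over all genes and adjusted over the list alone, and K07A3.3 did not pass (0.00 ± 0.10, -0.05 with the term; camera adjusted p = 1.83e-10, adjusted p = 0.0151 with an estimated correlation). Of 12 import genes 9 rose (10 adjusted over the list alone), among them ZK370.8 (0.78 ± 0.06; 0.44 with the term) and E04A4.5 (0.40 ± 0.04; camera adjusted p = 0.000414, adjusted p = 0.0872 with an estimated correlation). Of 12 mitochondrially encoded genes 8 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 3.28e-07, adjusted p = 0.231 with an estimated correlation).

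Cycle and cytochrome P450 lists were called Up and the vitellogenin list Down in mrps-5 worms, and none of these calls held with an estimated correlation. Among tricarboxylic acid and glyoxylate cycle genes 13 of 25 rose, with aco-2 at 0.46 ± 0.04 and cts-1, the citrate synthase gene, at 0.32 ± 0.03 (camera adjusted p = 0.00296, adjusted p = 0.506 with an estimated correlation). Cytochrome P450 genes rose in 21 of 69 and fell in 16 (21 and 18 adjusted over the list alone; camera adjusted p = 1.20e-05, adjusted p = 0.171 with an estimated correlation). With the library-set term this list was not called and its direction turned (median -0.07, adjusted p = 0.675). Examples are cyp-14A4 at 5.13 ± 0.08, cyp-13A12 at 4.89 ± 0.16 and cyp-33C8 at 3.52 ± 0.05. The glucuronosyltransferase genes ugt-62 and ugt-19 rose by 3.25 ± 0.05 and 3.24 ± 0.07, in a list with 13 rises and 23 falls that camera did not call (adjusted p = 0.295). All 6 vitellogenin genes fell (median -0.25, -0.48 with the term; camera adjusted p = 3.53e-05, adjusted p = 0.375 with an estimated correlation), vit-3 by 1.04 ± 0.05. Cytosolic ribosome genes fell in 66 of 81 members and histone genes in 22 of 40, with camera adjusted p = 6.68e-09 and 0.000674 (adjusted p = 0.762 and 0.536 with an estimated correlation). With the term their medians were 0.02 and -0.06 and neither was called. Large rises were also seen in F22B3.7 (5.25 ± 0.16), B0205.13 (4.86 ± 0.09) and clec-4 (4.34 ± 0.09). Large falls were in thn-1 (-2.69 ± 0.12), pud-4 (-2.303 ± 0.07), dhs-26 (-2.29 ± 0.07), pud-3 (-2.15 ± 0.08) and ugt-53 (-2.04 ± 0.09). The sqst-1 gene, which encodes a selective autophagy receptor, rose by 0.42 ± 0.04 here and by 1.01 ± 0.04 in cco-1 worms, in an autophagy list that camera called in neither (adjusted p = 0.749 and 0.959).

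The responses to both mitochondrial clones overlapped. Of the genes that rose, 2597 rose in both, against 719 for independent lists of these sizes (3795 × 3115 / 16435), and 2548 fell in both, against 691; 44 went opposite ways. Both comparisons share the empty vector libraries. In 20 simulations where no gene differed, this sharing alone gave a mean correlation of 0.512. It gave at most 1 shared gene, but hardly any gene can be called there, so that count is no chance value for the overlap. The correlation of the log2 changes across genes, which are not independent replicates, was 0.804, and their covariance was 0.212 against a simulated 0.0315. The 3 empty vector libraries cannot be split between the comparisons, so part of the excess may come from shared controls and from the library sets.

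The direct comparison of mrps-5 with cco-1 worms lies within 1 library set and separates the arms by yolk, lipid and heat shock genes. vit-3 was higher in mrps-5 worms by 2.85 ± 0.05 (adjusted p = 1.53e-31, n = 3 per group), vit-4 by 2.41 ± 0.06 and fat-7 by 3.002 ± 0.08. hsp-16.2 was lower by 3.26 ± 0.11 and hsp-16.41 by 2.97 ± 0.13. In all 1108 genes were higher and 825 lower. All 6 vitellogenin genes were higher (camera adjusted p = 2.97e-163, adjusted p = 8.84e-09 with an estimated correlation). So were 7 of 12 mitochondrially encoded genes (9 adjusted over the list alone; adjusted p = 1.62e-13, adjusted p = 0.0235 with an estimated correlation), with ctc-2 at 1.52 ± 0.07 and ctc-3 at 1.02 ± 0.09. Of the lipid genes 25 of 81 were higher and 6 lower (adjusted p = 4.03e-05, adjusted p = 0.0188 with an estimated correlation). Of the innate immunity genes 62 were higher and 27 lower, with lys-7 at 2.08 ± 0.05 (adjusted p = 0.00214, adjusted p = 0.0213 with an estimated correlation). Of 14 heat shock genes 4 were lower (adjusted p = 1.49e-08, adjusted p = 7.70e-05 with an estimated correlation). Of 18 DAF-16 associated genes 7 were higher, such as mtl-1 (1.72 ± 0.18), and 2 lower. Their median of -0.004 differed in sign from the test (Up, adjusted p = 0.00113, adjusted p = 0.0496 with an estimated correlation) and becomes 0.002 with RLE scaling. The antioxidant list was called here alone among the comparisons (3 of 19 higher, gst-10 at 1.54 ± 0.06 and gst-4 at 0.74 ± 0.06; adjusted p = 0.0108, adjusted p = 0.0524 with an estimated correlation). Camera also called, as Up, cytosolic ribosome (median 0.10), cytochrome P450 (0.18), glucuronosyltransferase (0.14), hypoxia (0.11) and one-carbon genes (0.11), with adjusted p = 0.00701, 0.00701, 0.00214, 0.00483 and 0.041, and adjusted p = 0.944, 0.312, 0.312, 0.0945 and 0.211 with an estimated correlation. Of the chaperones clpp-1 was lower (-0.17 ± 0.05) and hsp-6 did not pass (0.04 ± 0.05, adjusted p = 0.775). The other extremes were asm-3 (2.95 ± 0.08) and thn-2 (2.83 ± 0.12) among the higher genes, and F26E4.16 (-6.86 ± 0.52), F33H12.7 (-3.37 ± 0.14) and the heme-responsive gene hrg-2 (-2.81 ± 0.10) among the lower ones.

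In cbp-1 worms the vitellogenin and intestine lists were called Down and single genes rose by large factors. vit-3 and vit-4 fell by 3.78 ± 0.06 and 4.01 ± 0.06 (adjusted p = 9.36e-37 and 1.95e-32, n = 3 per group), the peptide transporter gene pept-1 by 1.99 ± 0.04 and the proton pump gene vha-6 by 1.75 ± 0.04. The F-box gene fbxa-75 rose by 8.83 ± 0.30, F26F2.1 by 7.17 ± 0.16, F22G12.1 (pals-14) by 7.05 ± 0.08, C17H1.6 (pals-5) by 6.87 ± 0.19 and B0348.2 by 6.83 ± 0.12. Large falls were in the lectin genes clec-190 (-7.46 ± 0.14) and clec-222 (-6.15 ± 0.11), dhs-26 (-7.37 ± 0.12), C40H1.7 (-6.49 ± 0.22) and tbh-1 (-6.77 ± 0.06), which encodes an enzyme of octopamine synthesis. In all 4969 genes rose and 4677 fell, and 1283 and 1384 of these by at least 2-fold. All 6 vitellogenin genes fell (median -3.003; camera adjusted p = 3.30e-37, adjusted p = 0.000473 with an estimated correlation). Of the intestine list 12 of 19 genes fell while 3 rose (12 and 4 adjusted over the list alone; adjusted p = 5.49e-06, adjusted p = 0.00863 with an estimated correlation). The metallothionein gene mtl-1 was among the rises (3.62 ± 0.08).

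Ribosome, oxidative phosphorylation and one-carbon lists were called Down in cbp-1 worms, within 1 library set, and these calls did not hold with an estimated correlation. Cytosolic ribosome genes fell in 78 of 81 members (rps-18 at -0.49 ± 0.04; adjusted p = 5.14e-05, adjusted p = 0.703 with an estimated correlation). Mitochondrial ribosome genes fell in 51 of 70 (mrps-26 at -0.44 ± 0.04; adjusted p = 0.018, adjusted p = 0.605 with an estimated correlation), and nuclear oxidative phosphorylation genes in 46 of 53 (gas-1 at -0.51 ± 0.03; adjusted p = 0.00335, adjusted p = 0.684 with an estimated correlation). Of 20 one-carbon and transsulfuration genes 11 fell and 4 rose, with the methionine cycle gene sams-1 at -1.51 ± 0.04 and cth-1 at -2.03 ± 0.05 (adjusted p = 0.018, adjusted p = 0.229 with an estimated correlation). The chaperones and proteases went both ways, with 3 rises and 7 falls over all genes and adjusted over the list alone, and camera did not call them (adjusted p = 0.51). Here hsp-60 gave -0.64 ± 0.12, hsp-6 -0.30 ± 0.05 and K07A3.3 0.36 ± 0.09. Of 12 import genes 10 fell, in a list that was not called (adjusted p = 0.16), with tomm-40 at -0.35 ± 0.04.

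Endoplasmic reticulum, autophagy and glutathione transferase lists were called Up in cbp-1 worms, and these calls also ended with an estimated correlation. Of 16 endoplasmic reticulum stress genes 12 rose and 1 fell (13 rose adjusted over the list alone, camera adjusted p = 0.0285, adjusted p = 0.55 with an estimated correlation). The choline kinase gene ckb-2 was at 2.40 ± 0.07 and the BiP gene hsp-4 at 0.47 ± 0.03. Of 31 autophagy and lysosome genes 22 rose and 5 fell, with sqst-1 at 1.92 ± 0.04, lgg-1 at 1.00 ± 0.04 and the cathepsin gene cpl-1 at -0.94 ± 0.04 (adjusted p = 0.0333, adjusted p = 0.229 with an estimated correlation). Glutathione transferase genes rose in 22 of 42 and fell in 10 (gst-20 at 2.85 ± 0.06, gst-27 at -1.58 ± 0.06; adjusted p = 0.00724, adjusted p = 0.468 with an estimated correlation). Single genes of lists that camera did not call moved far. The iron and manganese transporter gene smf-3 rose by 3.63 ± 0.06, fmo-2 by 3.93 ± 0.09, cyp-14A5 by 4.31 ± 0.05 and cpt-4 by 4.37 ± 0.10. The ferritin gene ftn-1 fell by 5.26 ± 0.38.

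Calls between the libraries labelled atfs-1 RNAi and the empty vector depended on the library-set term, with which 1 atfs-1 library is set against 3 and fewer differences can pass. Y19D10B.4 rose by 1.54 ± 0.11 (adjusted p = 4.20e-13, n = 3 per group; 1.42 with the library-set term, adjusted p = 7.33e-11) and F58G6.9 fell by 1.16 ± 0.08 (-1.21 with the term, adjusted p = 7.33e-11). hsp-16.41 and hsp-16.2 rose by 1.65 ± 0.19 and 1.38 ± 0.18 (1.53 and 1.56 with the term) and T16G1.7 by 0.63 ± 0.07 (0.45). Without the term 911 genes rose and 861 fell (51.4% rose, 61.8% with upper-quartile scaling); with it 18 rose and 36 fell, and 50 genes were called the same way in both. Leaving out the first library gave 4874 changed genes, and leaving out the replicate numbered 2 gave 155. The heat shock list was called in both fits (5 of 14 rose and 1 fell, 6 and 2 adjusted over the list alone; camera adjusted p = 0.000194, adjusted p = 0.00934 with an estimated correlation). With the term 2 members rose (adjusted p = 1.72e-05).

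Several calls in these libraries were lost with the term. rpl-37 rose by 2.01 ± 0.37 without the term and 0.09 with it. drd-10 (0.80 ± 0.12, 0.42) and tra-1 (0.65 ± 0.13, 0.10) also lost their calls. So did C53C7.5 (-0.91 ± 0.23, -0.12), the mitochondrially encoded nduo-6 (-0.76 ± 0.18, -0.33) and Y82E9BR.22 (-0.76 ± 0.14, -0.29). Without the term camera also called, as Down, glycolysis (adjusted p = 0.00102), nuclear oxidative phosphorylation (2.25e-09), both ribosome lists (5.68e-07 mitochondrial, 4.98e-11 cytosolic), one-carbon and transsulfuration (0.0476), oocyte and early embryo (0.00668) and histones (0.000458), and, as Up, cytochrome P450 (0.00876). With an estimated correlation their adjusted p were 0.428, 0.428, 0.35, 0.554, 0.428, 0.554, 0.428 and 0.428. The cytosolic ribosome list was called Up with the term (adjusted p = 7.86e-07), the opposite direction, and the other 7 were not called. The term also added 5 calls: chaperones, mitochondrially encoded and lipid genes as Down and collagen and sperm genes as Up (adjusted p = 0.0397, 0.0397, 0.00299, 0.00174 and 0.00106, and adjusted p = 0.311, 0.893, 0.0412, 0.893 and 0.893 with an estimated correlation). Among the chaperones hsp-60, hsp-6 and ymel-1 rose (0.47 ± 0.12, 0.16 ± 0.05 and 0.15 ± 0.04) without the term and not with it (-0.06, -0.05 and -0.03). The 6 vitellogenin genes had a median of 0.03 (adjusted p = 0.306), with vit-5 at 0.15 ± 0.06 (adjusted p = 0.105; -0.03 with the term).

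With the cbp-1 clone added, intestine, chaperone and vitellogenin lists were called Down in both arms. With an estimated correlation the chaperone call ended in both arms and the vitellogenin call in the cco-1 arm. hsp-6 fell by 0.50 ± 0.05 in the cco-1 arm and 0.43 ± 0.05 in the mrps-5 arm (adjusted p = 7.14e-12 and 2.71e-10, n = 3 per group). hsp-60 fell by 0.69 ± 0.12 and 0.62 ± 0.12, and dnj-10 by 0.49 ± 0.04 and 0.43 ± 0.04. vha-6 fell by 2.22 ± 0.04 and 2.16 ± 0.04, pept-1 by 2.24 ± 0.04 and 2.22 ± 0.04, and vit-4 by 1.80 ± 0.06 and 1.95 ± 0.06. The lipase-related gene lips-11 rose by 7.28 ± 0.24 and 7.48 ± 0.26, and the methyltransferase gene comt-4 by 7.23 ± 0.12 and 6.09 ± 0.11. In the cco-1 arm 3602 genes rose and 4159 fell, and in the mrps-5 arm 3189 rose and 3851 fell. The rising share of these calls, 46.4% and 45.3%, became 53.2% and 56.1% with upper-quartile scaling, so neither direction is the larger under every scaling. Both arms shared 2532 rises and 3077 falls, against 699 and 975 for independent lists, and the log2 changes correlated at r = 0.900 across genes, which are not independent replicates.

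Chaperone, import, oxidative phosphorylation, cycle and ribosome lists were called Down in both arms with cbp-1, and these list calls did not hold with an estimated correlation. Of the 12 chaperones and proteases 8 fell in the cco-1 arm and 9 in the mrps-5 arm (10 and 9 adjusted over the list alone; adjusted p = 0.03 and 0.0346, and adjusted p = 0.37 and 0.44 with an estimated correlation). ymel-1 did not pass in either (-0.02 ± 0.04 and -0.03 ± 0.04). Of 12 import genes 10 and 11 fell (adjusted p = 0.00573 and 0.00621, adjusted p = 0.137 and 0.143 with an estimated correlation), with tin-44 at -0.47 ± 0.04 and -0.37 ± 0.04. Of 53 oxidative phosphorylation genes 41 and 46 fell (adjusted p = 0.00179 and 2.36e-06, adjusted p = 0.496 and 0.44 with an estimated correlation), with gas-1 at -0.42 ± 0.03 and -0.63 ± 0.03. Of 70 mitochondrial ribosome genes 50 and 52 fell and mrps-14 gave -0.70 ± 0.04 and -0.66 ± 0.04 (adjusted p = 0.00573 and 0.0175, adjusted p = 0.395 and 0.475 with an estimated correlation). Cycle genes fell in 16 and 20 of 25, with the aconitase gene aco-1 at -1.31 ± 0.03 and -1.42 ± 0.04 (adjusted p = 0.03 and 0.00336, adjusted p = 0.395 and 0.319 with an estimated correlation). Cytosolic ribosome genes fell in 72 and 74 of 81 (rpl-27 at -0.40 ± 0.04 and -0.45 ± 0.04; adjusted p = 0.00166 and 1.88e-05, adjusted p = 0.695 and 0.569 with an estimated correlation).

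Intestine genes kept their call with an estimated correlation in both arms with cbp-1, with 14 and 14 of 19 falling and 3 and 4 rising (adjusted p = 1.66e-09 and 8.66e-14, adjusted p = 0.00104 and 0.00013 with an estimated correlation). mtl-1 was again among the rises (4.86 ± 0.11 and 3.94 ± 0.09). All 6 vitellogenin genes fell in each arm (medians -0.92 and -1.36; adjusted p = 2.19e-07 and 6.69e-14, adjusted p = 0.137 and 0.0382 with an estimated correlation). Glucuronosyltransferase genes fell in 38 and 38 of 63 (ugt-46 at -2.18 ± 0.05 and -2.29 ± 0.05; adjusted p = 0.00626 and 0.000137, adjusted p = 0.37 and 0.247 with an estimated correlation). One-carbon genes fell in 9 and 9 of 20 (cth-1 at -1.59 ± 0.05 and -2.46 ± 0.05; adjusted p = 0.0483 and 0.00599, adjusted p = 0.299 and 0.137 with an estimated correlation). Muscle genes fell in 17 and 19 of 28 (myo-3 at -0.67 ± 0.04 and -0.52 ± 0.04; adjusted p = 0.0389 and 0.0388, adjusted p = 0.395 and 0.475 with an estimated correlation). Autophagy and lysosome genes rose in 20 and 23 of 31 (sqst-1 at 0.93 ± 0.04 and 1.23 ± 0.04; adjusted p = 0.00686 and 0.00435, adjusted p = 0.137 and 0.0918 with an estimated correlation).

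Some lists were called in 1 arm with cbp-1. In the cco-1 arm endoplasmic reticulum genes rose in 13 of 16 (ckb-2 at 2.06 ± 0.06). The hypoxia list was called Up, with smf-3 (5.86 ± 0.07) and fmo-2 (3.25 ± 0.08), although ftn-1 fell by 5.83 ± 0.45. Histone genes rose in 23 of 40. For these 3 lists adjusted p were 0.00394, 0.00573 and 0.0483, and adjusted p = 0.23, 0.137 and 0.54 with an estimated correlation. In the mrps-5 arm lipid genes fell in 38 of 81 (fat-2 at -1.84 ± 0.03) and collagens in 83 of 161 (col-101 at -1.07 ± 0.04). RNA interference genes rose in 15 of 37 (sago-2 at 1.54 ± 0.05, ppw-1 at 1.17 ± 0.04). Their adjusted p were 0.0388, 0.00336 and 0.0192, and adjusted p = 0.309, 0.569 and 0.461 with an estimated correlation. A test of the difference between arms called endoplasmic reticulum, hypoxia and collagen genes (adjusted p = 3.44e-05, 1.05e-06 and 1.29e-05, and 0.0764, 0.0186 and 0.579 with an estimated correlation). It did not call lipid, histone or RNA interference genes (adjusted p = 0.784, 0.245 and 0.231). The cbp-1 effect itself differed between arms in 902 genes (588 higher and 314 lower in the cco-1 arm). fbxa-75 (8.21 ± 0.28), C17H1.6 (7.15 ± 0.17) and F26F2.1 (7.14 ± 0.14) were among the large rises in the cco-1 arm, and eol-1 (6.45 ± 0.09), F26F2.3 (6.38 ± 0.19) and B0348.2 (6.12 ± 0.11) those in the mrps-5 arm. The immune gene dod-24 fell far in both (-6.03 ± 0.15 and -7.04 ± 0.15). Other large falls were cyp-13A7 (-5.32 ± 0.17) and tbh-1 (-5.16 ± 0.05) in the cco-1 arm and F22B3.7 (-5.52 ± 0.17) in the mrps-5 arm, followed there by clec-190 (-5.52 ± 0.19). Y39B6A.21 fell in both (-5.07 ± 0.13 and -5.49 ± 0.17).

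In the mixtures labelled with atfs-1, the cytosolic heat shock list was called Up and the mitochondrial chaperone and import lists Down in both arms. hsp-16.2 rose by 3.56 ± 0.06 in the cco-1 arm and 5.72 ± 0.09 in the mrps-5 arm (adjusted p = 3.25e-36 and 3.34e-37, n = 3 per group). hsp-16.41 rose by 4.46 ± 0.07 and 6.03 ± 0.10, and hsp-70 by 4.41 ± 0.08 and 3.21 ± 0.09. hsp-6 fell by 0.45 ± 0.05 and 0.34 ± 0.05, dnj-10 by 0.62 ± 0.04 and 0.52 ± 0.04, and cyp-14A4 by 6.13 ± 0.10 and 5.81 ± 0.09. The atfs-1 count was not lower in these groups, but reads from the fed clone were not told apart from worm reads. These values therefore compare the libraries by label only. In the cco-1 arm 1474 genes rose and 1884 fell, and in the mrps-5 arm 1125 rose and 1640 fell. Both arms shared 739 rises and 1128 falls, against 101 and 188 for independent lists (r = 0.672 across genes), and the effect differed between arms in 573 genes (303 higher and 270 lower in the cco-1 arm).

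The chaperone and import lists fell in both arms with atfs-1 and kept their calls with an estimated correlation. Of the 12 chaperones and proteases 10 fell in the cco-1 arm and 9 in the mrps-5 arm (12 and 11 adjusted over the list alone; adjusted p = 3.56e-06 and 4.69e-07, adjusted p = 0.0409 and 0.0267 with an estimated correlation). hsp-60 did not pass in either (-0.31 ± 0.12 and -0.15 ± 0.12). Import genes fell in 10 and 6 of 12 (ZK370.8 at -0.63 ± 0.06 and -0.52 ± 0.06; adjusted p = 1.45e-06 and 0.000185, adjusted p = 0.00572 and 0.0267 with an estimated correlation). Of 14 heat shock genes 11 and 9 rose (adjusted p = 7.25e-51 and 2.90e-55, adjusted p = 1.14e-10 and 5.74e-11 with an estimated correlation). Cytochrome P450 genes fell in 21 and 17 of 69 and rose in 14 and 10 (cyp-13A12 at -6.96 ± 0.22 and -6.03 ± 0.18; adjusted p = 5.47e-12 and 1.77e-10, adjusted p = 0.00572 and 0.0215 with an estimated correlation). The mrps-5 arm median of 0.02 differs in sign from the test. Autophagy and lysosome genes rose in 15 and 12 of 31 (sqst-1 at 1.06 ± 0.04 and 0.72 ± 0.04; adjusted p = 6.89e-05 and 0.00028, adjusted p = 0.00765 and 0.0215 with an estimated correlation).

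Several further lists moved the same way in both arms with atfs-1, and these calls did not hold with an estimated correlation. Glucuronosyltransferase genes fell in 17 and 13 of 63 (ugt-62 at -3.81 ± 0.05 and -3.58 ± 0.05, adjusted p = 0.143 and 0.109 with an estimated correlation). Glycolysis genes fell in 9 and 8 of 19 (gpd-2 at -0.66 ± 0.04 and -0.55 ± 0.04, adjusted p = 0.178 and 0.295 with an estimated correlation). Mitochondrial ribosome genes fell in 50 and 19 of 70 (mrps-14 at -0.69 ± 0.04 and -0.46 ± 0.04, adjusted p = 0.0949 and 0.44 with an estimated correlation). Collagens fell in 62 and 62 of 161 (col-62 at -0.49 ± 0.07 and -0.64 ± 0.07, adjusted p = 0.788 and 0.44 with an estimated correlation). Sperm genes fell in 32 and 34 of 71 (spe-15 at -0.28 ± 0.04 and -0.35 ± 0.04, adjusted p = 0.385 and 0.165 with an estimated correlation). Endoplasmic reticulum genes rose in 11 and 9 of 16 (pdi-6 at 0.18 ± 0.03 and 0.19 ± 0.03, adjusted p = 0.371 and 0.295 with an estimated correlation). Proteasome genes rose in 11 and 11 of 33 (pbs-7 at 0.16 ± 0.03 and 0.12 ± 0.03, adjusted p = 0.552 and 0.381 with an estimated correlation). With the preset correlation the adjusted p of these 7 lists ran from 4.69e-07 for sperm genes in the mrps-5 arm to 0.0238 for endoplasmic reticulum genes in the cco-1 arm.

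Other lists were called in 1 arm with atfs-1. In the cco-1 arm 8 of 20 one-carbon genes fell (cth-1 at -1.24 ± 0.05; adjusted p = 0.000996, adjusted p = 0.0466 with an estimated correlation), as did 25 of 81 lipid genes (elo-6 at -0.75 ± 0.04; adjusted p = 0.0175, adjusted p = 0.162 with an estimated correlation). Of the intestine genes 5 rose and 7 fell (ges-1 at -1.86 ± 0.08; adjusted p = 0.00815, adjusted p = 0.0949 with an estimated correlation), and their median of 0.02 differs in sign from the Down call. In the mrps-5 arm 6 of 12 mitochondrially encoded genes fell (atp-6 at -0.40 ± 0.09; adjusted p = 0.0423, adjusted p = 0.534 with an estimated correlation). Of the innate immunity genes 26 rose and 53 fell (clec-66 at -2.09 ± 0.06; adjusted p = 0.0197, adjusted p = 0.0919 with an estimated correlation), and their median of 0.01 differs in sign from the Down call. Oocyte and early embryo genes rose in 3 of 29 (nos-2 at 0.17 ± 0.05; adjusted p = 0.0271, adjusted p = 0.635 with an estimated correlation), and the cytosolic ribosome list was called Up (median 0.07; adjusted p = 0.0375, adjusted p = 0.812 with an estimated correlation). A test of the difference between arms called one-carbon, intestine and innate immunity genes (adjusted p = 0.000547, 0.0056 and 0.0147), and none of them with an estimated correlation (adjusted p = 0.0637, 0.0857 and 0.0857). It did not call lipid, mitochondrially encoded, oocyte and early embryo or cytosolic ribosome genes (adjusted p = 0.0621, 0.562, 0.911 and 0.504). F22B3.7 fell far in both arms (-7.79 ± 0.16 and -7.46 ± 0.21), with clec-4 (-5.61 ± 0.09 and -4.20 ± 0.08), cyp-13A7 (-5.63 ± 0.19) in the cco-1 arm and F58G6.9 (-4.48 ± 0.07) in the mrps-5 arm. hsp-16.48 (3.59 ± 0.09 and 3.90 ± 0.12), B0348.2 (3.76 ± 0.10) and Y94H6A.10 (2.15 ± 0.04) were among the large rises.

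**Figure D3:**
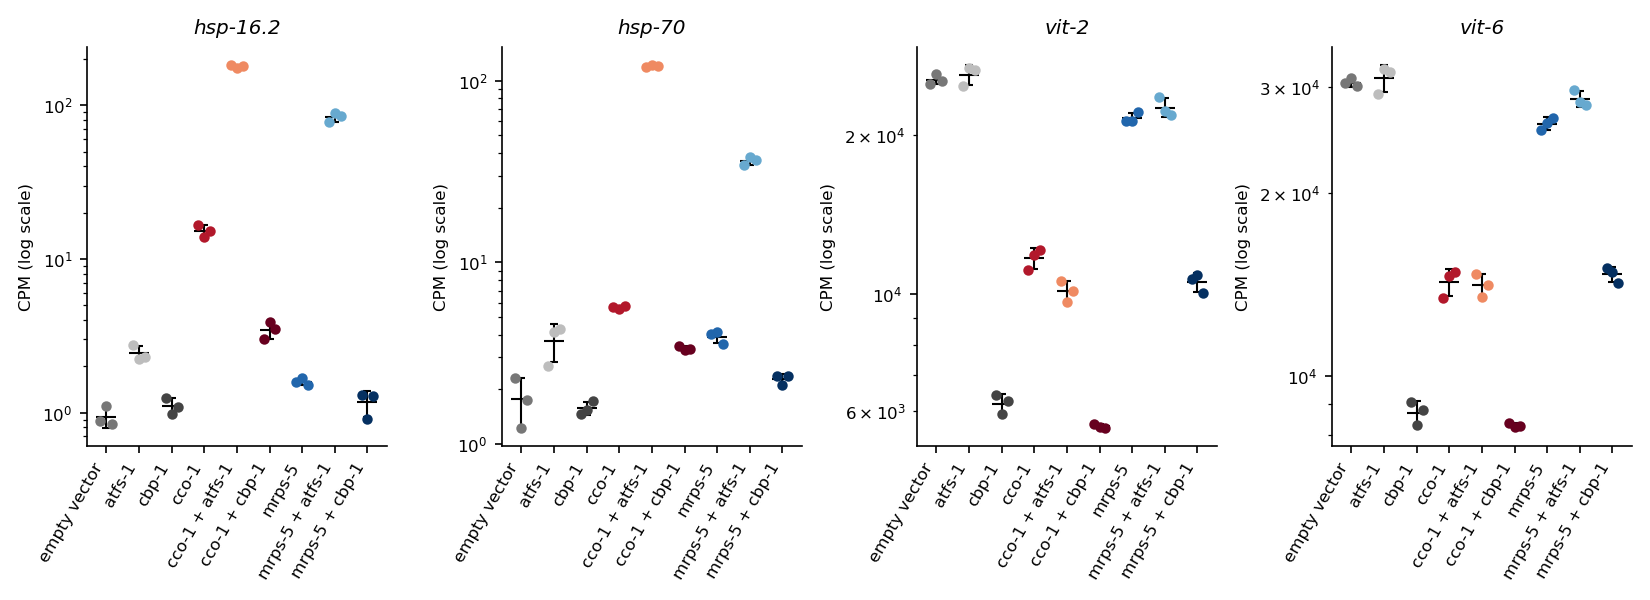
CPM of hsp-16.2, hsp-70, vit-2 and vit-6 on log scales in each of the 27 libraries by group (points), with the mean and SD of 3 libraries. Both heat shock genes are highest where atfs-1 was added to cco-1 or mrps-5, and both vitellogenins are lower in cco-1 and cbp-1 worms than in the empty vector.

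The mixtures with cbp-1 and with atfs-1 were compared directly within each arm. hsp-16.2 was lower with cbp-1 than with atfs-1 by 5.70 ± 0.07 and 6.18 ± 0.09 in the cco-1 and mrps-5 arms (n = 3 per group). Of the heat shock list 11 and 10 of 14 genes were lower (adjusted p = 2.06e-24 and 2.04e-15, adjusted p = 5.05e-08 and 2.04e-06 with an estimated correlation). hsp-6 did not pass in either arm (-0.05 ± 0.05 and -0.10 ± 0.05; adjusted p = 0.459 and 0.0904). Y22D7AL.10 (the mitochondrial Hsp10 gene) and hsp-60 were lower with cbp-1 (-0.42 ± 0.06 and -0.50 ± 0.06 for the first, -0.38 ± 0.12 and -0.47 ± 0.12 for the second). ymel-1 was higher (0.18 ± 0.04 and 0.22 ± 0.04). Intestine genes were lower with cbp-1 in 12 and 14 of 19 (adjusted p = 1.50e-05 and 7.65e-12, adjusted p = 0.0117 and 0.000179 with an estimated correlation). All 6 vitellogenins were lower (adjusted p = 6.02e-06 and 9.24e-17, adjusted p = 0.358 and 0.0117 with an estimated correlation). Oxidative phosphorylation genes were lower in 39 and 47 of 53 (adjusted p = 0.84 and 0.713 with an estimated correlation) and cytosolic ribosome genes in 76 and 77 of 81 (adjusted p = 0.84 and 0.747 with an estimated correlation). In the cco-1 arm the list tests also called proteasome genes lower (29 of 33; adjusted p = 0.0412, adjusted p = 0.84 with an estimated correlation). They called cytochrome P450 (34 of 69 higher; adjusted p = 0.00126, adjusted p = 0.358 with an estimated correlation) and hypoxia genes higher (smf-3 at 4.97 ± 0.07; adjusted p = 0.0352, adjusted p = 0.358 with an estimated correlation). In the mrps-5 arm they called cycle genes lower (19 of 25; adjusted p = 0.00515, adjusted p = 0.566 with an estimated correlation). Whether these 4 lists differ between arms was not tested. In all 3556 genes were higher and 3762 lower with cbp-1 in the cco-1 arm, and 3476 and 3849 in the mrps-5 arm. The higher share of these calls, 48.6% and 47.5%, became 54.2% and 58.5% with upper-quartile scaling. fbxa-75 (9.56 ± 0.32) and lips-11 (7.87 ± 0.26 and 7.33 ± 0.25) were among the large positive values, and Y19D10B.4 (-8.08 ± 0.21) and C40H1.7 (-6.14 ± 0.19 and -5.87 ± 0.19) among the large negative ones.

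The interaction terms ask whether cbp-1 or atfs-1 clones acted differently with and without a mitochondrial clone. The labels give no share of bacteria for cbp-1 or atfs-1 alone, so the doses alone and in the mixtures may differ. For cbp-1, dnj-10 had an interaction of -0.37 ± 0.05 with cco-1 and -0.31 ± 0.05 with mrps-5 (adjusted p = 7.43e-07 and 2.13e-05), C34C12.8 -0.33 ± 0.06 and -0.43 ± 0.06, and clpp-1 -0.25 ± 0.07 and -0.28 ± 0.07. hsp-60 did not pass (-0.04 ± 0.17 and 0.02 ± 0.17). The chaperone list was called Down in both (7 and 4 of 12 lower; adjusted p = 0.0435 and 0.0495, adjusted p = 0.507 and 0.515 with an estimated correlation). Vitellogenins had positive interactions in all 6 members, vit-3 at 3.07 ± 0.07 and 2.33 ± 0.07 (adjusted p = 8.03e-72 and 2.26e-57, adjusted p = 5.52e-06 and 2.77e-05 with an estimated correlation). Cytochrome P450 genes were lower in 25 and 27 of 69 (cyp-13A5 at -4.26 ± 0.14 and -4.05 ± 0.17), sperm genes in 50 and 36 of 71, collagens in 64 and 73 of 161 and glutathione transferases in 13 and 16 of 42. These lists were called Down in both arms, with adjusted p = 0.398 and 0.078, 0.164 and 0.341, 0.961 and 0.522, and 0.398 and 0.479 with an estimated correlation. The glucuronosyltransferase list was called Down in both (adjusted p = 0.0133 and 4.21e-06, adjusted p = 0.507 and 0.245 with an estimated correlation), with a median of 0.06 of the opposite sign with cco-1. Molting genes were called in the mrps-5 interaction alone (13 of 28 lower, mlt-9 at -0.74 ± 0.14; adjusted p = 0.0169, adjusted p = 0.479 with an estimated correlation). Oocyte and early embryo genes were called Up in both (higher in 5 and 10 of 29; adjusted p = 0.0435 and 0.00074, adjusted p = 0.961 and 0.536 with an estimated correlation). Hypoxia and cytosolic ribosome genes were called Up with cco-1 (adjusted p = 0.0435 and 0.0435, adjusted p = 0.398 and 0.961 with an estimated correlation). Intestine and endoplasmic reticulum genes were called Down with mrps-5 (adjusted p = 0.0195 and 0.0339, adjusted p = 0.258 and 0.515 with an estimated correlation). The cbp-1 interactions with cco-1 and mrps-5 differ by the same quantity as the arms, and that test called molting, hypoxia, intestine and endoplasmic reticulum genes (adjusted p = 0.000523, 1.05e-06, 0.000155 and 3.44e-05; 0.141, 0.0186, 0.0389 and 0.0764 with an estimated correlation) but not cytosolic ribosome genes (adjusted p = 0.0719). In all 4088 genes had a called interaction with cco-1 (1582 higher, 2506 lower) and 3875 with mrps-5 (1334 and 2541; 34.4% higher, and 45.2% with DESeq2).

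For atfs-1 the interactions cross the library sets. hsp-6 had an interaction of -0.61 ± 0.07 with cco-1 and -0.50 ± 0.07 with mrps-5 (-0.40 and -0.29 with the library-set term), dnj-10 -0.63 ± 0.05 and -0.53 ± 0.05 (-0.58 and -0.48) and hsp-16.48 3.32 ± 0.21 and 3.63 ± 0.23 (3.47 and 3.78). The chaperones were lower in 11 and 9 of 12 (adjusted p = 2.50e-08 and 1.21e-09, adjusted p = 0.0151 and 0.0127 with an estimated correlation), and in 8 and 7 with the term. Heat shock genes were higher in 7 and 6 of 14 (adjusted p = 8.32e-08 and 1.24e-10, adjusted p = 0.000244 and 2.51e-05 with an estimated correlation), and in 6 and 6 with the term. Autophagy and lysosome genes were called Up in both (higher in 12 and 8 of 31; adjusted p = 0.000455 and 0.00337, adjusted p = 0.0211 and 0.104 with an estimated correlation). The cytosolic ribosome and histone lists were called Up in both without the term (medians 0.22 and 0.25, 0.31 and 0.28, adjusted p = 0.592 and 0.529, 0.451 and 0.476 with an estimated correlation) and in neither with it. Called in all were 2801 genes with cco-1 (1325 higher, 1476 lower) and 2258 with mrps-5 (1074 and 1184); with the term these were 1824 (892 and 932) and 1295 (554 and 741). Without the first library labelled atfs-1 RNAi they were 5128 and 4827. cyp-14A4 (-4.98 ± 0.29 and -4.66 ± 0.28), the cadmium-responsive gene cdr-2 (-3.87 ± 0.10 and -3.57 ± 0.10), R08F11.4 (-3.37 ± 0.10 and -3.33 ± 0.10) and clec-4 (-5.17 ± 0.20 and -3.76 ± 0.19) were among the large negative terms. Y41C4A.11 (3.31 ± 0.08 and 1.98 ± 0.08) was among the large positive ones. With the term clec-4 gave -4.84 and -3.44.

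Genes raised by the mitochondrial clones were often lower with either added clone. Of 426 genes raised at least 2-fold by cco-1, 230 (53.99%) were lower with cbp-1 and 186 (43.7%) with atfs-1 in the cco-1 arm, against 25.3% and 11.5% of all genes. Of 258 raised by mrps-5, 146 (56.6%) were lower with cbp-1 and 148 (57.4%) with atfs-1 in the mrps-5 arm, against 23.4% and 9.98% of all genes. Each pair of comparisons shares its mitochondrial libraries with opposite sign. In 20 simulations that kept the rise and left the mixture unchanged, at most 2.55% of the genes raised by cco-1 and 3.93% of those raised by mrps-5 were lower at the p limits of the real comparisons. Across arms, where no library is shared, 51.6% and 53.9% of the mrps-5 set were lower in the cco-1 arm with cbp-1 and atfs-1, and 48.8% and 40.4% of the cco-1 set in the mrps-5 arm. Camera called all 8 sets Down, with adjusted p of at most 7.02e-05, and at most 0.0344 with an estimated correlation. In the cco-1 set 141 genes were lower with both clones, and 146 were lower and 150 higher with cbp-1 than with atfs-1; in the mrps-5 set these numbers were 123, 55 and 88. Yet in cbp-1 worms without a mitochondrial clone 196 genes of the cco-1 set were higher than in the empty vector and 78 lower, and of the mrps-5 set 110 and 52. hsp-6 and dnj-10, below 2-fold, are outside both sets, and F22B3.7, cyp-14A4 and clec-4 are inside them.

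Of the 34 lists 4 were not called in any of the 15 comparisons without the library-set term. In cbp-1 worms neuron genes had a median of 0.24, with 30 of 61 higher (sbt-1 at 0.57 ± 0.05; adjusted p = 0.121), and with cbp-1 added to cco-1 a median of 0.16 (adjusted p = 0.0654). Mitochondrial stress regulators, among them dve-1 (-0.44 ± 0.07) and the prohibitin gene phb-1 (-0.40 ± 0.04), had a median of -0.08 in cbp-1 worms (adjusted p = 0.139) and 0.14 in cco-1 worms (adjusted p = 0.774). Germline proliferation and meiosis genes had medians of 0.02 in cco-1 and 0.05 in mrps-5 worms (adjusted p = 0.959 and 0.626), with glp-1 at 0.26 ± 0.04 and 0.23 ± 0.04, calls that ended with the library-set term (0.03 and 0.01, adjusted p = 0.739 and 0.952). Hypodermis genes had medians of 0.16 and 0.12 (adjusted p = 0.271 and 0.457), with rol-6 at 0.54 ± 0.09 and 0.29 ± 0.09, which also lost both calls with the term (0.25 and 0.01, adjusted p = 0.326 and 0.99).

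**Figure D4:**
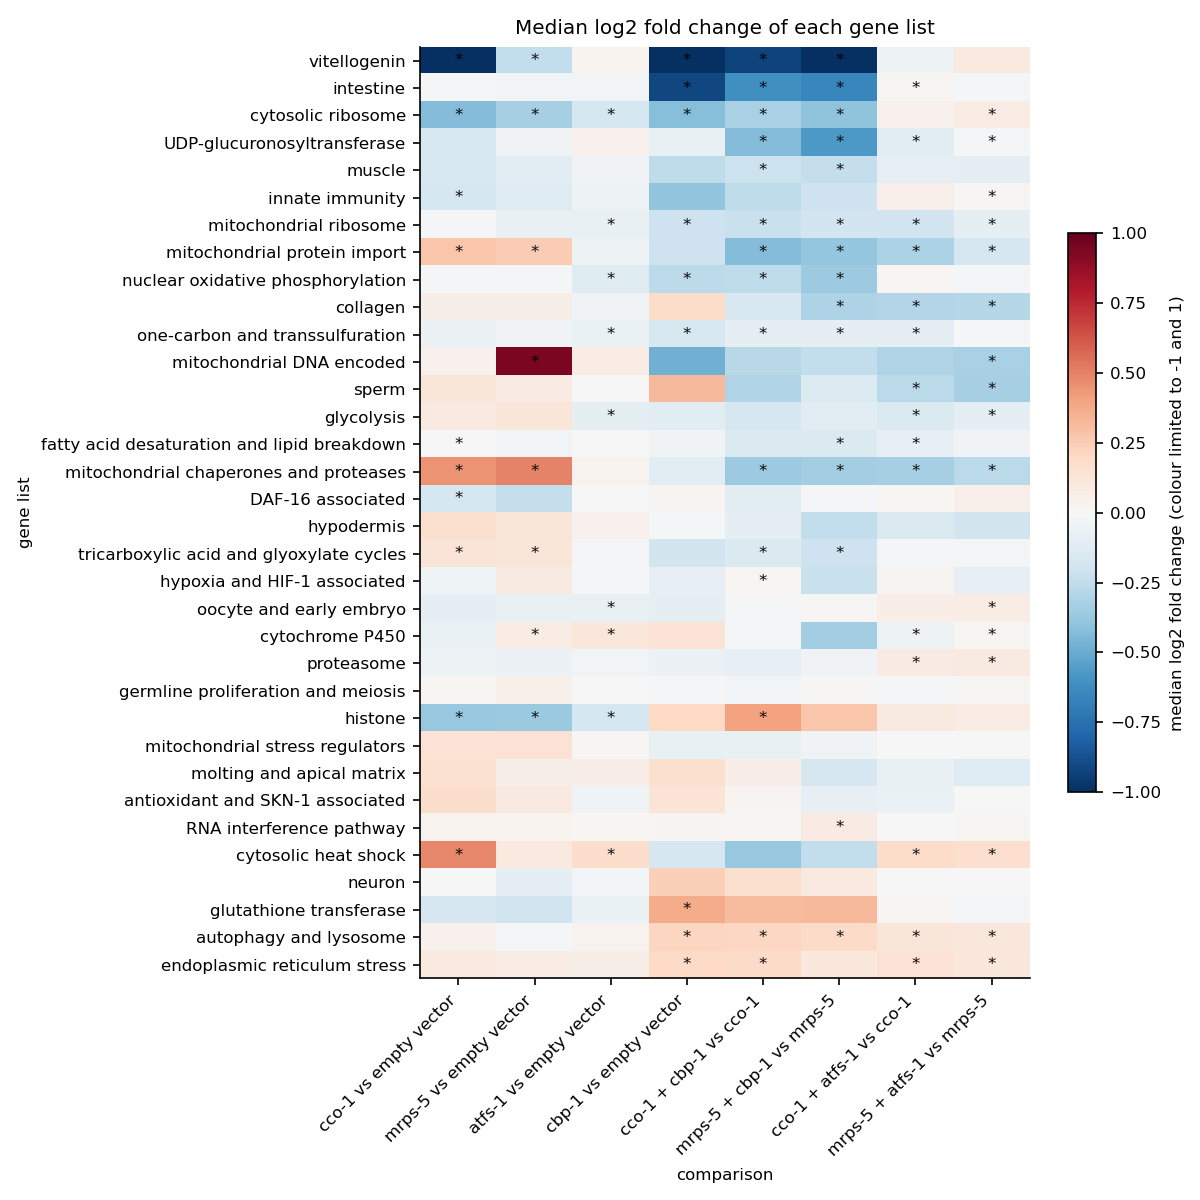
Median log2 fold change of each of 34 gene lists in 8 comparisons, in colour between -1 and 1; a star marks a camera adjusted p below 0.05. The chaperone and import lists are above 0 in cco-1 and mrps-5 worms and below 0 in the mixtures labelled with cbp-1 or atfs-1.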

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

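The 4 interaction terms and the percents below were planned; the tests of the difference between arms, the comparison of unused read classes, the equal effect of cbp-1, the handling of the heat shock groups and the aberrant library were chosen after the results were seen. A test of the difference itself called 4088 genes for cco-1 with cbp-1, 2801 for cco-1 with atfs-1, 3875 for mrps-5 with cbp-1 and 2258 for mrps-5 with atfs-1. Each term was also refitted with labels shuffled at random over all its groups, giving 25 groupings with the real one. Shuffling also breaks the effect of each clone alone and the library sets, so it does not imitate a lack of interaction. For cco-1 with cbp-1, 1 of 25, the real grouping, gave as many genes (highest other 3094). For cco-1 with atfs-1 this was also 1 of 25, with a highest other of 2760, close to the real count. Chance is left open for both. For mrps-5 with cbp-1, 3 of 25 gave as many (highest other 4779), and for mrps-5 with atfs-1, 2 of 25 (highest other 3268), so it is not excluded for these.

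The effect of the added clone differed between the cco-1 and mrps-5 arms in 902 genes for cbp-1 and 573 for atfs-1. Of these, 53 and 37 were called in opposite directions in both arms. Chosen after their values were seen, the protease gene asp-8 rose by 0.44 with cbp-1 in the cco-1 arm and fell by 1.31 in the mrps-5 arm, daao-1 by 1.08 and -0.67, and the glucuronosyltransferase gene ugt-16 went the other way (-0.68 and 0.73). With atfs-1 the acyl-CoA dehydrogenase gene acdh-1 fell by 2.21 in the cco-1 arm and rose by 0.37 in the mrps-5 arm, and dhs-25 gave -1.08 and 0.20. Reads left out of the gene counts stood above the empty vector in every library of 7 groups for the share without a feature and of 5 groups for the ambiguous share, which holds reads over more than 1 gene; these shares lie between 0.456% and 0.864% of reads and their source was not tested.

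Of the cytosolic heat shock genes 9 rose in both mixtures of cco-1 or mrps-5 that are labelled with atfs-1. hsp-16.2, hsp-16.41, hsp-16.48, hsp-70 and F44E5.4 rose by at least 2.28, and hsp-1, daf-21, hsp-110 and dnj-13 by 0.10 to 0.17. A single aberrant library is argued against, since 6 of 6 mixture libraries lay above every cco-1 or mrps-5 library of their arm in the list's mean. Handling or temperature of these groups cannot be told apart from a response to the clones: without a mitochondrial clone, the median change of these 9 members was 0.115 with the library-set term, which sets 1 atfs-1 library against 3, and hsp-16.2 and hsp-16.41 alone were called (1.56 and 1.53). The smaller of the mixture medians, 2.28, is the value of F44E5.4, a gene below 1 CPM that lies between the strong and the weak members, so it describes no typical member. A heat shock response of worms with both disturbances may also give this pattern and was not tested further.

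Many genes raised by cco-1 were lower with cbp-1. If cbp-1 lowered them equally with and without cco-1, few would have a called interaction, but 64.8% of the 426 genes had a lower one, which argues against an equal effect as the cause. The interaction contains the libraries that selected these genes; over 199 genes raised in mrps-5 worms against the libraries labelled atfs-1 RNAi, which share no library with it, 62.8% had a lower one. Part of this comes from cbp-1 alone, where 196 of the 426 genes were higher than in the empty vector and 78 lower (median 0.49). A larger cbp-1 dose in the mixture could not be examined, since the labels give no share for cbp-1 alone. A need for cbp-1 in the response to mitochondrial disturbance was not tested.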

How the results depend on the processing

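The library-set term, the raised set from that fit and the difference between arms were chosen after the data were seen; the other alternatives were planned. Outside the leave-one-out fits, 154 of the values of the comparisons stayed within 1.5 times the reported count or within the spread, and 54 moved; the cause was not tested except where fewer libraries or genes enter. No scaling moved the median of all genes by more than 0.1: the largest shifts were 0.0313 with RLE, 0.0542 with upper-quartile and 0.0315 with DESeq2 factors, and 1 of 175 called list medians changed sign with each. The share of calls that were higher moved by up to 9.67 percentage points with RLE, 10.7 with DESeq2 and further with upper-quartile scaling (47.5% to 58.5% for the cbp-1 against the atfs-1 mixture in the mrps-5 arm), so which direction holds more calls depends on the scaling where the share is near even, such as for the cbp-1 mixtures.

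With the library-set term the changed genes were 2691 for cco-1, 1602 for mrps-5 and 54 for the libraries labelled atfs-1 RNAi against the empty vector, and 1824 and 1295 for the atfs-1 interactions with cco-1 and mrps-5. With only the groups compared, so fewer libraries, the atfs-1 count was 28 and its mrps-5 interaction 1306. Leaving out each library in turn gave 155 (without atfs-1 replicate 2) to 4874 (without replicate 1) for the atfs-1 comparison (182 without atfs-1 replicate 3, and 868, 831 and 453 without empty vector replicates 1, 2 and 3), 2085 (without atfs-1 replicate 3) to 5128 (without replicate 1) for its cco-1 interaction, and 1566 (without atfs-1 replicate 3) to 4827 (without replicate 1) for its mrps-5 interaction. The other 20 results stayed within 1.5 times or within the spread when any 1 library was left out.

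The percents of raised genes that were lower moved with the choice of the raised set. For genes raised by cco-1 and lower in the cco-1 arm with cbp-1, they were 65.2 with the stricter filter, 64.7 with the library-set term, 63.6 with the raised set from that fit, 65.6 with a raised set at a log2 change of 2, 64.8 by the interaction term and 62.1 with only the groups compared; with atfs-1 they were 55.6, 49.4, 49.1, 62.4 and 37.6 in the first 5 of these and 38.8 without a filter. For the same genes in the mrps-5 arm with cbp-1 they were 62.3, 61.0, 59.5, 60 and 55.6, and 42.6 without a filter; with atfs-1 58.5, 50.2, 49.4, 56 and 35.4, then 45.3 with only the groups compared, 34.6 without a filter and 33.8 with DESeq2. For genes raised by mrps-5, the percents in the mrps-5 arm with cbp-1 were 75.2, 75.7, 75.7, 68.6, 64.3 and 66.98 in the order first given; with atfs-1 they were 78.5, 77.9, 77.9 and 74.3 in the first 4, and 67.9 with only the groups compared. In the cco-1 arm these genes gave 67.8, 70.6, 69.9 and 58.6 with cbp-1 and 73.6, 75, 75 and 75.7 with atfs-1, then 61.3 and 62.7 with only the groups compared.

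Of the values of 315 named genes outside the leave-one-out fits, 2462 kept direction and call, 32 lost the call (17 with the library-set term, 11 with only the groups compared), 15 gained it and 8 changed sign. When 1 library was left out, 2023 kept both, 32 lost the call, 1 gained it and 8 changed sign. Over all comparisons 175 list tests were called, and an estimated correlation ended 135 of these calls and left 40. Of the 179 list tests named in the text 154 were called, of which it ended 116. Over all their alternatives 545 values kept direction and call, 139 lost the call, 17 gained it and 15 turned. Of the named genes, sign changes were confined to values near 0 and to the library-set term. K07A3.3 in mrps-5 worms became 0.0189 with upper-quartile scaling and ran from -0.0838 to 0.0891 when 1 library was left out. ymel-1 with cbp-1 became 0.0106 and 0.0212 in the cco-1 and mrps-5 arms with upper-quartile scaling, and the interaction of hsp-60 for mrps-5 with cbp-1 became -0.00195 with the stricter filter and ran from -0.00706 to 0.0641 when 1 library was left out. With the library-set term hsp-6, hsp-60, ymel-1 and vit-5 gave -0.0498, -0.0649, -0.0296 and -0.0283 in the libraries labelled atfs-1 RNAi. That term also turned the direction of 15 list tests: chaperones, mitochondrially encoded, collagen, cytosolic ribosome, histone, nuclear oxidative phosphorylation and vitellogenin for atfs-1 (adjusted p = 0.0397, 0.0397, 0.00174, 7.86e-07, 0.29, 0.855 and 0.434), autophagy, collagen, histone and oocyte for cco-1 (0.763, 0.0567, 0.986 and 0.785), cytosolic ribosome for the interaction of cco-1 and atfs-1 (0.773), and glucuronosyltransferase, cytochrome P450 and cytosolic ribosome for mrps-5 (0.68, 0.675 and 0.431).

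The replicates' numbers do not pair libraries: 0 of 8 comparisons met the rule, with correlations of -0.08 to 0.02, and the own number was best in 11 of 24. A replicate block left all 23 results within 1.5 times or within the spread and ended the call of 5 list tests.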

Other observations

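The tests of the library sets, of shared vitellogenin reads and of the intestinal share in cbp-1 worms were chosen after the results were seen; the intestinal share and development in cco-1 worms and the regroupings of libraries were planned. The cbp-1 homologs rose in cbp-1 worms: cbp-2 went from 11.4 ± 0.175 to 62 ± 2.61 CPM (mean ± SD, n = 3; 2.44 ± 0.06, adjusted p = 2.78e-32) and F40F12.7 (cbp-3) rose by 3.09 ± 0.05 (adjusted p = 3.14e-36). F40F12.7 also rose without a cbp-1 clone, by 1.90 ± 0.06 in cco-1 and 1.34 ± 0.06 in mrps-5 worms (1.71 and 1.15 with the library-set term), where cbp-2 did not rise (-0.06 ± 0.07 and -0.17 ± 0.07). With cbp-1 added, F40F12.7 rose by 0.78 ± 0.05 in the cco-1 arm and 1.42 ± 0.05 in the mrps-5 arm.

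Yolk transcripts and reads without a unique alignment moved together. vit-2 and vit-6 had 25515 ± 529 and 30464 ± 494 CPM in the empty vector, 11674 ± 532 and 14303 ± 734 in cco-1 worms and 6190 ± 255 and 8709 ± 379 in cbp-1 worms. The share of reads without a unique alignment averaged 14.8% in the empty vector, 15.4% in the libraries labelled atfs-1 RNAi, 12.7% in mrps-5 worms, 8.19% in cco-1 worms and 7.96% in cbp-1 worms. Nearly identical vitellogenin copies would lose such reads, and changes of vit-3, vit-4 and vit-5 would then rest on the unique part of their reads.

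Vitellogenin transcripts fell in cco-1 and in cbp-1 worms. Reads shared among copies are argued against as the whole source, since vit-2 and vit-6, taken from general knowledge to be more distinct than vit-3, vit-4 and vit-5, fell as well, the smallest of these changes being -1.09. How alike the copies are was not measured. In cco-1 worms a smaller intestinal share is argued against. The intestine list had a median of -0.0114 with an interquartile range of 0.566, against a smallest vitellogenin change of -1.09. Delayed development is left open. The oocyte and early embryo list had a median of -0.0924 (quartiles -0.185 and 0.0415), but whether a short delay would lower this list was not tested. In cbp-1 worms the intestine list had a median of -0.908 with an interquartile range of 1.68 against a smallest vitellogenin change of -1.81, so a smaller intestinal share and lower yolk transcription cannot be told apart there. Lower yolk transcription in cco-1 worms may be a response to the clone, as a hypothesis from the same data.

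The 27 libraries fell into a pair of sets. A library preparation or sequencing difference with a trend over gene length could give their axis (rho -0.593, single libraries at most 0.321 in size). The labels name no batch. A mislabelled empty vector library as the first atfs-1 library is argued against, since over 79 genes called alike and at least 2-fold in both atfs-1 mixtures it lay 0.194 in their direction, against -0.011 to 0.026 for the empty vector libraries. The other atfs-1 libraries had a slope of 0.332 on the cco-1 and mrps-5 change, against -0.053 to 0.037 for single libraries. Both differences cross the same sets, which fixes this outcome, so a response to mitochondrial RNAi and another source of the sets cannot be told apart by it. The labels give these atfs-1 libraries no mitochondrial clone. No other biological explanation of the sets was tested.

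Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share below 0.05. In most comparisons the real split gave the most genes, 1 of 10, and the highest other split gave 0. These were cco-1, mrps-5 and cbp-1 against the empty vector, mixtures against their mitochondrial clone or each other, and mrps-5 against cco-1. For the libraries labelled atfs-1 RNAi against the empty vector, 3 of 10 splits gave at least the real 1772 genes. The highest other, 2794, puts the first atfs-1 library with empty vector replicates 1 and 3. It mixes the library sets as the real split does, with 3 libraries of the first set against 1 of that set and 2 of the second.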
